A study of Homo sapiens with 4 samples.

How the data were processed

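RNA from KYSE30 cells was profiled by sequencing in 4 libraries, 2 from cells with a negative-control short hairpin RNA (shNC) and 2 from cells with a short hairpin RNA against YY1 (shYY1). Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, cells with stable knockdown were selected with puromycin and libraries were made with an Illumina TruSeq RNA kit from total RNA. The extraction text in the labels speaks of retina tissue although the samples are labelled as a human cell line, so markers of retina were measured. The sequences of the hairpins and the strand setting of the counting are not given in the sources used here, so reads of a gene and of its antisense partner cannot be told apart.

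Per the submitters' processing notes, the tool was Bowtie 0.12.2 and the builds were mm8 and mm9, which are mouse builds. The deposited table holds 30716 human Ensembl gene IDs, so those notes cannot describe how this table was made, and its aligner, counter and build are not given in the sources used here. All 29871 of its gene IDs that are also in GENCODE 29 (GRCh38) lie on the same chromosome there, and 17586 have the same start and end. The authors deposited whole-number counts per gene for each library, which were used as they stand. The authors also deposited FPKM values per gene, which are scaled to gene length and library total, and these served as an alternative. Each column was assigned to its sample by name, and 0 columns belonged to other samples. Genes with reads shared by overlapping genes or near-identical copies are uncertain, because the rule for such reads is not given.

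Total counts ranged from 67390336 to 72499865 per library. A count of 3, the floor used for genes at 0 counts, corresponded to 0.0414 to 0.0445 CPM per library. These floors cover at best counting error, since reads without molecular identifiers are not independent molecules. The SDs and standard errors given below also include the spread between libraries.

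Genes were kept by edgeR's filterByExpr (minimum count 10, minimum total 15), which left 18035. The main comparison was edgeR's quasi-likelihood test (R 4.3.3, edgeR 4.0.16) with TMM factors (0.980 to 1.04), robust estimation, no block and Benjamini-Hochberg adjustment at 0.05. The common biological coefficient of variation was 20.2% and the fit had 2 residual degrees of freedom. Standard errors of log2 fold changes were derived from the fold change and the F statistic, and CPM values are TMM-scaled. Lists of genes were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, over lists with at least 5 tested members, beside camera with an estimated correlation and fry. Of the 38 lists, those of retina, stromal, immune and endothelial genes served as markers of other cells.

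The tests, lists, alternatives and the rule for named genes were fixed before the data were examined. Named are YY1, then genes from the 10 largest increases and 10 largest decreases among protein-coding genes with an adjusted p under 0.05, both libraries of a group on the same side of the other group, a mean of at least 5 CPM in the higher group and a symbol that is not a clone name. Named are further, in each list described, up to 4 members with the smallest adjusted p and up to 2 in the opposite direction, and the 5 most abundant genes called in each direction. NOLC1, MSMO1, EGFR and others meet more than 1 part of the rule. MX1, HERC5, MFAP5, SPECC1L-ADORA2A, TMEM189-UBE2V1, BACH1, KEAP1 and NFE2L2 lie outside that rule or were singled out after their values were seen.

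Alternatives were RLE factors, library totals alone, no filter (at least 1 count in total), at least 5 CPM in 2 libraries, DESeq2 1.42.0 (voom for lists), limma-trend on log2 CPM, the fit without robust estimation, each library left out, the replicate number as a block, and limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1) for genes at 1 FPKM or more in 2 libraries.

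On simulated counts for the comparison of shYY1 with shNC over 18035 genes, with 200 genes changed, the edgeR script recovered 24.0% of genes changed 1.5-fold and 63.0% of genes changed 2-fold, with 10 and 21 false calls. Among changed genes at 5 CPM or more it recovered 45.2% and 89.0%. The 10 false calls stood beside 48 true calls, and the 21 beside 126. In both simulations this is a larger share of false calls than the adjusted p threshold of 0.05 is meant to allow. The calls on the real counts may therefore also hold more false calls than that threshold states. The search for 3' UTR words was tested on the real 3' UTRs of 9619 genes with shuffled fold changes: a shift of -0.20 put on 1 word was recovered as -0.21, and the most negative t without it was -4.39.

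Words of 7 bases were counted in the annotated 3' UTR of the transcript with the longest coding sequence (GENCODE 29 basic set), in genes with a 3' UTR of at least 50 bases and a mean of at least 5 CPM, YY1 left out, and log2 fold change was regressed on each of 16252 words with length and GC content in the model (Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1). A gene without an annotated 3' UTR counted as not searched. KEGG and Reactome terms were read from the deposited table.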

Results

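RNA-seq was performed on KYSE30 cells, an established line from human esophageal squamous cell carcinoma (ESCC). The cells carried either a negative-control short hairpin RNA (shNC) or a short hairpin RNA against YY1 (shYY1), a zinc finger transcription factor that activates or represses many promoters. Each group had 2 libraries. The deposited table gave counts for 30716 genes, of which 3205 had 0 counts in all 4 libraries. Total counts were 67390336 and 72499865 in the shNC libraries and 71255363 and 69736613 in the shYY1 libraries, and 22159 to 22918 genes had at least 1 count in a library. The replicates of a group differed by more than sampling noise, with a chi-square per gene of 46.3 in shNC and 20.4 in shYY1, so the columns are not repeat sequencing of 1 library. This does not show separate samples, and each library was used as 1 sample because the labels list it as such. The labels do not say whether replicates were separate cultures, so all p-values measure only the spread between these samples, which may be technical.

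The comparison of shYY1 with shNC asks which transcripts differ between cells with these hairpins. Effects of the loss of YY1 and other effects of either hairpin cannot be told apart by it, so "after YY1 knockdown" below names the group and not the cause. For this reason 3' UTR words are given with named genes, and the search for them is described among the other observations. YY1 itself (ENSG00000100811, chromosome 14, 100238298 to 100282788, plus strand, in the coordinates of the deposited table) was measured before any other gene as a check of the labels. It was at 113 ± 4.23 CPM in shNC and 35.7 ± 1.96 CPM in shYY1 (SD, n = 2 each), with 8147 and 7960 counts in the shNC libraries and 2606 and 2344 in the shYY1 libraries. This was a log2 fold change of -1.67 ± 0.088 (SE), or 3.17-fold lower, with an adjusted p of 6.18e-05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 18035 tested genes. In that test 910 genes were higher and 883 lower after YY1 knockdown. Of these 1793 genes, 234 changed at least 2-fold, 82 higher and 152 lower. On simulated counts edgeR's test gave a larger share of false calls than its threshold allows, so the same may hold for these genes. All 1793 called genes had both shYY1 libraries on the same side of both shNC libraries. So did 54.9% of all tested genes, against 33.3% by chance. The median absolute log2 fold change of called genes was 0.56, and the median over all tested genes was -0.01. The number of called genes moved when a library was left out. Such a fit has 1 library in a group, so the number also moves with the loss of a sample. In each of these fits 0 of the called genes changed direction. DESeq2's Wald test called 1470 genes higher, and scaling by library totals alone moved the share of higher genes among the called genes from 50.8% to 40.3%. That share was 44.2% with limma-trend on log2(FPKM + 1), and it also moved with single libraries left out.

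HMOX1, which encodes the heme-degrading enzyme heme oxygenase 1, had the largest increase among the abundant protein-coding genes, 3.48 ± 0.163 on the log2 scale, or 11.2-fold, from 30.7 ± 6.04 to 343 ± 50.4 CPM (SD, n = 2 each; edgeR adjusted p = 0.000118). The next largest increases were in TM4SF1, a tetraspan membrane protein (log2 fold change 1.65 ± 0.088), OGFR, the opioid growth factor receptor (1.58 ± 0.114), and SDCBP2, a PDZ-domain protein (1.55 ± 0.20). CEMIP, which takes part in hyaluronan breakdown (2.90 to 8.22 CPM), HABP4 (1.43), the nucleolar phosphoprotein NOLC1 (1.32), FAM83A (1.31) and the forkhead factor FOXQ1 (1.30) were also among the 10 largest increases, with edgeR adjusted p-values from 6.18e-05 for TM4SF1 to 0.00818 for FAM83A. SDCBP2 and FAM83A were at 8.60 and 5.18 CPM in shYY1, so their values rest on far fewer counts than that of NOLC1 (201 to 500 CPM). The largest decrease was in LONRF1, a RING finger protein (-1.97 ± 0.238), followed by AP4S1, a subunit of an adaptor complex (-1.92 ± 0.209), and MSMO1, a sterol methyl oxidase of cholesterol synthesis (-1.81 ± 0.0955). TMBIM6, an endoplasmic reticulum membrane protein, fell from 847 ± 40.6 to 244 ± 11.5 CPM (SD) and its log2 fold change was -1.80 ± 0.0882. ZDBF2 (-1.71), the palmitoyltransferase ZDHHC20 (-1.59), the Wnt pathway scaffold APC (-1.58), the circadian transcription factor CLOCK (-1.58) and the p53 ubiquitin ligase MDM2 (-1.55) followed, with edgeR adjusted p-values from 6.18e-05 for MSMO1 and TMBIM6 to 0.00625 for ZDBF2. All of these 18 genes and YY1 were called with each of the 4 libraries left out in turn. The annotated 3' UTRs of LONRF1, AP4S1, MSMO1, TMBIM6, ZDBF2, APC, CLOCK and MDM2 hold the 7-base word TTCAGAA or TCAGAAA, and that of ZDHHC20 holds neither. Of all 9619 genes searched, 2915 hold TTCAGAA or TCAGAAA, so a word in a single gene is common. A long 3' UTR may hold one by length alone, and those of MDM2 and CLOCK have 10837 and 7512 bases. Among the increases, the 3' UTRs of HABP4 and NOLC1 hold the 7-base word TCGGAGA, and that of NOLC1 holds TTCAGAA as well.

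**Figure D1:**
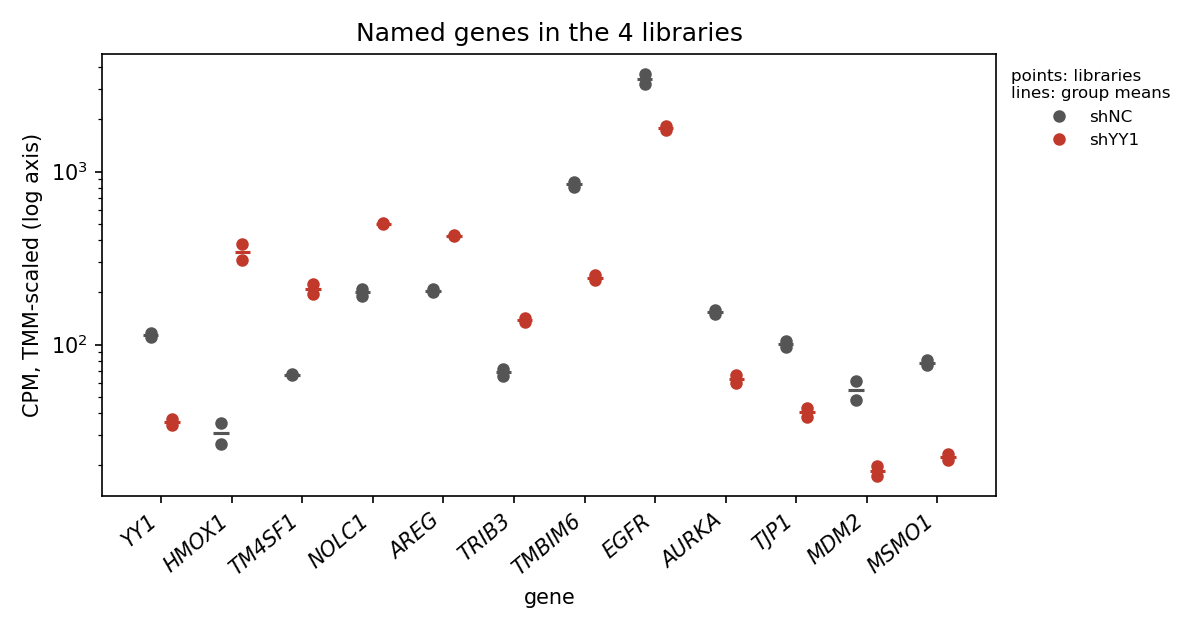
CPM of 12 named genes (log axis) in the 2 shNC (gray) and 2 shYY1 (red) libraries, with points for libraries and short lines for group means. HMOX1 moved from 30.7 to 343 CPM and YY1 from 113 to 35.7 CPM, and in each gene both libraries of a group lie on the same side of the other group.

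Among the most abundant called genes, EGFR, the epidermal growth factor receptor, fell from 3438 ± 309 to 1791 ± 63.3 CPM (log2 fold change -0.94 ± 0.105, edgeR adjusted p = 0.0015), and its 3' UTR holds TTCAGAA and TCAGAAA. The chaperonin HSPD1 (0.46), the actin-binding protein CTTN (0.35), the retinaldehyde dehydrogenase ALDH1A3 (0.50), the hyaluronan receptor CD44 (0.50) and the translation initiation factor EIF3B (0.35) were the most abundant genes that rose. MT-CO1 (-0.66), MT-CO2 (-0.54), MT-ND1 (-0.58) and PTMA (-0.32) were the other most abundant genes that fell. Apart from EGFR, the nuclear genes lost their calls without shYY1 replicate 1 and without shYY1 replicate 2, with edgeR adjusted p-values of 0.270 and 0.191 for HSPD1, 0.403 and 0.349 for CTTN, 0.118 and 0.150 for ALDH1A3, 0.0676 and 0.129 for CD44, 0.291 and 0.355 for EIF3B, and 0.431 and 0.461 for PTMA. Their log2 fold changes stayed of similar size, without these libraries in turn 0.43 and 0.50 for HSPD1, 0.32 and 0.37 for CTTN, 0.51 and 0.49 for ALDH1A3, 0.53 and 0.47 for CD44, 0.36 and 0.34 for EIF3B, and -0.32 and -0.32 for PTMA. The 3' UTR of CTTN holds TTCAGAA, those of HSPD1, ALDH1A3, CD44 and EIF3B hold neither word, and that of PTMA was too short to search.

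Of 38 gene lists fixed in advance, 37 had enough tested members, and camera with a preset correlation of 0.01 called 17 higher and 3 lower after YY1 knockdown. With an estimated correlation camera called 0 lists (2 at an unadjusted p under 0.05). Fry's one-way test, which asks whether the members of a list move one way, called 0 (12 at an unadjusted p under 0.05). Its mixed test, which asks whether members change in any direction, called 29 of the 37 lists. The fit had only 2 residual degrees of freedom. For hypoxia-induced genes the estimated correlation was -0.006, below the preset 0.01, yet camera's unadjusted p went from 4.02e-06 to 0.0362. So for that list, failing with an estimated correlation does not show that correlation among members undid the call. Over the lists the estimates ranged from -0.117 for immune markers to 0.861 for cytosolic ribosomal proteins. They were 0.836 for mitochondrially encoded mRNAs and 0.674 for respiratory chain subunits. For lists with such high estimates the preset 0.01 may be far too low, and camera's p-values with it too small. The group descriptions below rest on the members called singly, with camera's preset correlation beside them under that limit.

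Camera with the preset correlation called the list of amino acid and unfolded protein stress genes higher. Of 33 tested members, 14 rose (15 adjusted over the list alone) and 19 did not pass, with a median log2 fold change of 0.30 (camera adjusted p = 2.77e-08; adjusted p = 0.535 with an estimated correlation). The pseudokinase TRIB3 (1.01 ± 0.0844), the eIF2 alpha phosphatase subunit PPP1R15A (0.84 ± 0.107), the transcription factor ATF4 (0.56 ± 0.0881) and its partner DDIT3 (1.09 ± 0.183) led the list. Of 29 immediate early and AP-1 genes, 17 rose and 2 fell (17 and 3 adjusted over the list alone), with a median of 0.49 (camera adjusted p = 2.77e-08; adjusted p = 0.535 with an estimated correlation). The EGFR ligands AREG (1.06 ± 0.0772, from 205 to 426 CPM) and EREG (0.90 ± 0.080) and the MAP kinase phosphatases DUSP5 (0.87 ± 0.0857) and DUSP6 (0.82 ± 0.0826) had the smallest adjusted p-values. JUND (-0.52) and ETV4 (-0.35) were the 2 that fell. Both lost that call without shYY1 replicate 1 (-0.49, edgeR adjusted p = 0.0767 for JUND and -0.36, 0.222 for ETV4), and ETV4 lost it also without shYY1 replicate 2 (-0.33, 0.295). The 3' UTR of ETV4 holds TCAGAAA and that of JUND holds neither word. DUSP6, which rose, also holds TCAGAAA.

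Camera with the preset correlation also called the lists of NRF2 targets, hypoxia-induced genes, cholesterol synthesis and autophagy higher. Of 28 NRF2 targets and glutathione genes, 7 rose (9 adjusted over the list alone) and 21 did not pass, with a median of 0.23 (camera adjusted p = 3.25e-06; adjusted p = 0.535 with an estimated correlation). HMOX1 led this list, followed by GCLM, the modifier subunit of the enzyme that starts glutathione synthesis (0.78 ± 0.0767), and OSGIN1 (0.83 ± 0.101). Of 24 hypoxia-induced genes, 6 rose (8 adjusted over the list alone) and 18 did not pass, with DDIT4 (0.76 ± 0.0805), NDRG1 (0.65 ± 0.0843) and the oxidase ERO1A (0.60 ± 0.091) in front (camera adjusted p = 2.12e-05; adjusted p = 0.535 with an estimated correlation). Of 25 cholesterol synthesis genes, 8 rose and 1 fell (13 and 3 adjusted over the list alone), with a median of 0.27 (camera adjusted p = 3.48e-05; adjusted p = 0.535 with an estimated correlation). INSIG1, a sterol-regulated brake on the pathway (1.17 ± 0.081), HMGCS1 (0.83 ± 0.0821) and mevalonate kinase MVK (0.56 ± 0.0843) rose, whereas MSMO1 was the member that fell. Of 22 genes of fatty acid synthesis and desaturation, 2 rose and 1 fell (4 and 2 adjusted over the list alone), and camera did not call the list (adjusted p = 0.333). Among the genes that rose here, the 3' UTRs of GCLM and ERO1A hold TTCAGAA, and that of ERO1A also TCAGAAA. Of 33 autophagy and lysosome genes, 7 rose (10 adjusted over the list alone) and 26 did not pass, among them the autophagosome protein MAP1LC3B (0.69 ± 0.0809) and the cargo receptor SQSTM1 (0.69 ± 0.109) as the leading members that rose (camera adjusted p = 6.41e-05; adjusted p = 0.535 with an estimated correlation).

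Inflammatory and interferon-linked lists passed camera in the same way. Of 24 NF-kB targets and cytokines, 8 rose (9 adjusted over the list alone) and 16 did not pass, with a median of 0.52 (camera adjusted p = 1.26e-05; adjusted p = 0.535 with an estimated correlation). IER3 (0.68 ± 0.0832), the cytokine LIF (0.52 ± 0.0928), the chemokine CXCL8 (2.21 ± 0.393, from 0.637 to 2.95 CPM) and the ubiquitin-editing enzyme TNFAIP3 (0.76 ± 0.145) led. Of 31 interferon-stimulated genes, 8 rose and 1 fell (12 and 1 adjusted over the list alone), with a median of 0.37 (camera adjusted p = 0.00122; adjusted p = 0.535 with an estimated correlation). IFIT2 (1.11 ± 0.128), OASL (1.14 ± 0.153), OAS1 (0.88 ± 0.134) and IFIT3 (0.90 ± 0.161) rose and were at 27.0, 17.5, 21.4 and 14.4 CPM in shYY1. MX1 and HERC5 were listed at 0 counts in both shNC libraries. In the shYY1 libraries MX1 had 18 and 47 counts and HERC5 21 and 23. By group means they were at least 10.99-fold and 7.40-fold higher in shYY1, taking 3 counts per library as the floor. The median of the list was 0.37 also with both at that bound. The member that fell was STAT2 (-0.51 ± 0.107), which lost its call without shYY1 replicate 1 (-0.51, edgeR adjusted p = 0.0923) and without shYY1 replicate 2 (-0.50, 0.0884), and whose 3' UTR holds neither word. Of 18 antigen presentation genes, 4 rose and 14 did not pass (5 higher and 1 lower adjusted over the list alone), led by HLA-E (0.52 ± 0.0932; camera adjusted p = 0.00318 for the list, and 0.146 among genes without the 3' UTR words; adjusted p = 0.547 with an estimated correlation).

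Lists of the translation and respiration machinery moved by small amounts. Of 78 cytosolic ribosomal protein genes, 74 had a positive log2 fold change with a median of 0.15, but edgeR, DESeq2 and limma-trend called 0 of them, with 1, 13 and 4 at an unadjusted p under 0.05 (0 adjusted over the list alone in edgeR). Camera nevertheless called the list higher (adjusted p = 7.08e-06; adjusted p = 0.754 with an estimated correlation). Of 76 nuclear-encoded respiratory chain subunits, 4 rose (3 adjusted over the list alone) and 72 did not pass, with a median of 0.11 (camera adjusted p = 0.000334; adjusted p = 0.779 with an estimated correlation). Of 77 mitochondrial ribosomal protein genes, 8 rose and 3 fell (8 and 3 adjusted over the list alone), and the smallest adjusted p-values belonged to MRPL33 (-1.17 ± 0.11) and MRPS9 (-0.75 ± 0.095), which fell while the list was called higher (camera adjusted p = 0.00152; adjusted p = 0.740 with an estimated correlation). The 3' UTR of MRPL33 holds TTCAGAA and TCAGAAA, and that of MRPS9 holds TCAGAAA. Without shNC replicate 1 these lists no longer passed camera: over the alternatives their adjusted p-values ranged up to 0.247 for cytosolic ribosomal proteins, 0.472 for respiratory chain subunits and 0.150 for mitochondrial ribosomal proteins, each highest without that library.

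All 13 mitochondrially encoded mRNAs had negative log2 fold changes, with a median of -0.49, and 4 of them fell (13 adjusted over the list alone): MT-CO1 (-0.66 ± 0.153), MT-ND6 (-0.49 ± 0.123), MT-CO2 (-0.54 ± 0.142) and MT-ND1 (-0.58 ± 0.153). Camera called the list lower (adjusted p = 1.93e-06; adjusted p = 0.547 with an estimated correlation). Mitochondrial transcripts made up 4.76% and 3.60% of counts in the shNC libraries and 2.76% and 3.14% in the shYY1 libraries. The mitochondrial ribosomal RNAs MT-RNR1 (log2 fold change 0.01) and MT-RNR2 (-0.15) did not pass edgeR's test. Without shNC replicate 1, the library with the highest share, the median of the 13 mRNAs in log2 CPM was -0.29, against -0.50 with all libraries, and the edgeR adjusted p-values were 0.496 for MT-ND6, 0.540 for MT-CO2 and 0.541 for MT-ND1, with log2 fold changes of -0.38, -0.38 and -0.37. MT-CO1 kept its call there (-0.40, adjusted p = 0.00155), and camera still called the list lower (9.43e-05), as in all 12 alternatives (3.64e-07 to 0.00326). MT-ND6, MT-CO2 and MT-ND1 lost their calls also without shNC replicate 2 (0.291, 0.298 and 0.263) and without shYY1 replicate 1 (0.323, 0.407 and 0.338). MT-CO1 lost its call without shYY1 replicate 1 (0.170) and shYY1 replicate 2 (0.123), and MT-CO2 without shYY1 replicate 2 (0.0567). Scaling by library totals alone ended the call of all 4, with adjusted p-values from 0.0525 for MT-ND6 to 0.0865 for MT-ND1, but their log2 fold changes were not smaller (-0.54 for MT-ND6 to -0.71 for MT-CO1) and camera called the list lower (1.35e-06).

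Camera called the list of mitotic genes lower, although most members did not pass. Of 46 G2/M and mitosis genes, 7 fell, 2 rose and 37 did not pass (8 and 2 adjusted over the list alone), with a median of -0.12 (camera adjusted p = 0.00576; adjusted p = 0.535 with an estimated correlation). The mitotic kinase AURKA (-1.29 ± 0.0849, from 154 to 63.3 CPM) and the centromeric histone CENPA (-1.13 ± 0.122) fell most clearly, and the 3' UTRs of both hold TTCAGAA and TCAGAAA. The proliferation antigen MKI67 (-0.47 ± 0.0959), with neither word, and ANLN (-0.51 ± 0.106), with both, also fell, whereas KIF2C (0.33 ± 0.0869) and the survivin gene BIRC5 (0.36 ± 0.0951), with TCAGAAA, rose. Without shYY1 replicate 2 the edgeR adjusted p-values of MKI67, ANLN, KIF2C and BIRC5 were 0.171, 0.251, 0.455 and 0.221, with log2 fold changes of -0.43, -0.37, 0.27 and 0.36. Without shYY1 replicate 1 the adjusted p-values of MKI67, KIF2C and BIRC5 were 0.0791, 0.172 and 0.213, with log2 fold changes of -0.51, 0.39 and 0.36. ANLN lost its call also without shNC replicate 1 (-0.43, adjusted p = 0.214) and shNC replicate 2 (-0.57, 0.122). The camera adjusted p of the list ranged from 0.000646 to 0.136 over the alternatives and missed 0.05 without shNC replicate 2 (0.0873) and without shYY1 replicate 2 (0.136). Of 44 G1/S and DNA replication genes, 3 rose and 2 fell (5 and 4 adjusted over the list alone), with a median of 0.00, and the replicative helicase subunit MCM6 fell by 0.69 ± 0.0754 on the log2 scale. Its 3' UTR holds TTCAGAA and TCAGAAA.

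**Figure D2:**
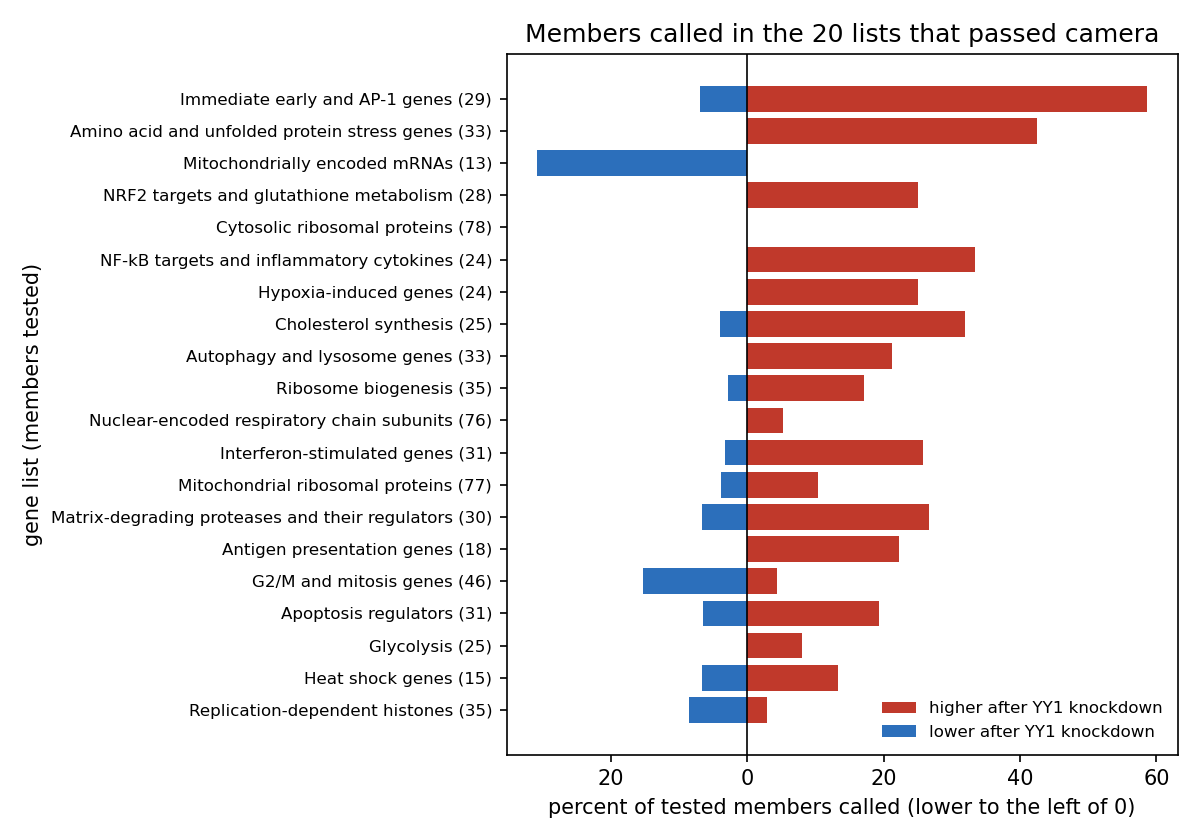
Percent of tested members of each list called higher (red, right of 0) or lower (blue, left of 0) by edgeR, for the 20 lists that passed camera with the preset correlation, ordered by camera p, with the number of tested members in parentheses. The immediate early and AP-1 list had 58.6% of its members higher, and the mitochondrially encoded mRNAs had 30.8% lower.

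Basal squamous, junction and adhesion genes moved in both directions, and of the lists in this paragraph only that of proteases passed camera. Of 21 integrin and laminin genes, 2 rose and 1 fell (4 and 1 adjusted over the list alone; camera adjusted p = 0.424). Of 29 basal squamous genes, 2 rose, the hemidesmosomal collagen COL17A1 (0.74 ± 0.084) and the Notch ligand JAG1 (0.62 ± 0.0747), and 1 fell, EGFR (5 and 1 adjusted over the list alone; camera adjusted p = 0.155). Of 26 squamous differentiation genes, 5 rose (7 higher and 1 lower adjusted over the list alone), led by the transcription factor KLF4 (0.62 ± 0.0899) and the cornified envelope protein IVL (0.63 ± 0.106; camera adjusted p = 0.109 for the list, 0.0290 to 0.315 over the alternatives, lowest on FPKM). Of 35 epithelial junction genes, 1 rose and 3 fell, and the tight junction scaffold TJP1 (-1.31 ± 0.0953) fell most clearly (1 and 3 adjusted over the list alone; camera adjusted p = 0.389, and 0.0117 without shNC replicate 2, where the list was higher; range over the alternatives 0.0117 to 0.885). The 3' UTR of TJP1 holds TTCAGAA and TCAGAAA. Of 31 mesenchymal genes, 2 rose and 3 fell (2 and 3 adjusted over the list alone; camera adjusted p = 0.815), with the receptor kinase AXL (-0.83 ± 0.0909) and the lysyl oxidase LOXL2 (-0.66 ± 0.113) falling and neither holding a word. The list's median (0.01) and mean (0.11) were positive and camera's direction was negative. Of 30 matrix-degrading proteases and regulators, 8 rose and 2 fell (9 and 2 adjusted over the list alone), with the metalloproteases ADAM15 (0.93 ± 0.0904) and ADAM19 (0.58 ± 0.0826) and the inhibitor TIMP3 (0.66 ± 0.0989), which holds TCGGAGA, among those that rose (camera adjusted p = 0.00152; adjusted p = 0.535 with an estimated correlation). The 3' UTRs of COL17A1 and ADAM19, which rose, hold TCAGAAA. Of 24 YAP/TEAD targets, 4 rose and 7 fell (5 and 11 adjusted over the list alone), including TGFB2 (-0.92 ± 0.128), whose 3' UTR holds TTCAGAA, and AMOTL1, whose 3' UTR holds TTCAGAA and TCAGAAA and which rose (0.60 ± 0.0759; camera adjusted p = 0.056 for the list, 0.0258 to 0.187 over the alternatives, 0.0411 with library totals alone, and 0.0125 among genes without the 3' UTR words).

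Several further lists had few called members, and all but that of p53 targets passed camera. Of 35 ribosome biogenesis genes, 6 rose and 1 fell (9 and 1 adjusted over the list alone), led by NOLC1 (camera adjusted p = 0.00012; adjusted p = 0.535 with an estimated correlation). Of 31 apoptosis regulators, 6 rose and 2 fell (10 and 2 adjusted over the list alone; camera adjusted p = 0.00845, 0.0943 without shYY1 replicate 2 and 0.0526 at 5 CPM or more, range 0.0012 to 0.0943; adjusted p = 0.553 with an estimated correlation). Of 25 glycolysis genes, 2 rose (2 adjusted over the list alone). Camera's adjusted p for the list was 0.0137, with 0.0571 on FPKM + 1 and 0.177 among genes without the 3' UTR words. It was 0.653 with an estimated correlation. The glycolysis list passed in 8 of 12 alternatives fixed in advance. Its failures included the fits without shNC replicate 1, without shYY1 replicate 1 and on FPKM + 1. Of 15 heat shock genes, 2 rose and 1 fell (4 and 2 adjusted over the list alone; camera adjusted p = 0.0353; adjusted p = 0.553 with an estimated correlation). The heat shock list passed in 7 of 12 alternatives fixed in advance. It failed without shYY1 replicate 1 (0.216), at 5 CPM or more (0.157) and on FPKM + 1 (0.186) and FPKM + 0.1 (0.178), with a range of 0.0116 to 0.216. Among genes without the 3' UTR words its adjusted p was 0.0931. Of 35 replication-dependent histone genes, 3 fell and 1 rose (3 and 1 adjusted over the list alone; camera adjusted p = 0.0479; adjusted p = 0.535 with an estimated correlation). The median of their mean levels in shNC was 0.853 CPM, so many of these genes lay below 5 CPM there. The histone list passed in 5 of 12 alternatives. It failed without shNC replicate 1 (0.0841), shNC replicate 2 (0.196) or shYY1 replicate 2 (0.107), with library totals alone (0.0818), without a filter (0.224) and at 5 CPM or more (0.274), with a range of 0.0247 to 0.274. Of 26 p53 targets, 4 rose and 2 fell (9 and 4 adjusted over the list alone), with GDF15 (1.17 ± 0.114) higher and MDM2 and CCNG1 (-0.77 ± 0.0837) lower (camera adjusted p = 0.0503, below 0.05 in 3 of 12 alternatives, 0.0211 without shNC replicate 2, 0.0495 with RLE factors and 0.0423 without a filter; range 0.0211 to 0.253). The 3' UTR of CCNG1 holds neither word.

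The lists of YY1 partners in chromatin complexes did not pass camera. Of 16 tested genes of the YY1 family and the INO80 remodelling complex, edgeR called only YY1, and DESeq2 called 2 higher and 1 lower (1 lower adjusted over the list alone in edgeR; camera adjusted p = 0.761). The median of that list was 0.07 and its mean -0.003. Of 31 Polycomb group genes, 4 rose and 3 fell (5 and 6 adjusted over the list alone; camera adjusted p = 0.859), including the PRC2 cofactor JARID2 (0.67 ± 0.0917) and the PRC2 core subunit SUZ12 (-0.70 ± 0.118), whose 3' UTR holds TTCAGAA and TCAGAAA.

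Markers of other cell types did not separate the groups, apart from MFAP5. Of 10 tested retina genes edgeR, DESeq2 and limma-trend called 0, with 0 at an unadjusted p under 0.05, and the highest group mean was 2.38 CPM. The 7 immune markers and 6 endothelial markers tested also had 0 calls in edgeR, DESeq2 and limma-trend and 0 at an unadjusted p under 0.05. Their highest group means were 8.09 CPM for the immune and 40.7 CPM for the endothelial markers, the latter in EGFL7 (38.9 CPM in shNC). Of 4 stromal markers tested, edgeR called MFAP5, which was listed at 0 counts in both shNC libraries and had 24 and 16 counts in the shYY1 libraries, and DESeq2 and limma-trend called 0. By group means MFAP5 was at least 6.70-fold higher in shYY1 at a floor of 3 counts. It lost its call whichever of the 4 libraries was left out, with edgeR adjusted p-values of 0.127 and 0.103 without shNC replicates 1 and 2 and 0.219 and 0.0877 without shYY1 replicates 1 and 2. In the whole test, 20 called genes were listed at 0 counts in 1 group, with at most 158 counts in any library, and no fold is given for them unless a bound is stated. Read-through genes that share exons with their neighbors are uncertain: SPECC1L-ADORA2A had 0 and 3022 counts in the shNC libraries and 0 and 2409 in the shYY1 libraries.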

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

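Chosen only after results were seen were the subsets without 3' UTR words and without overlapping genes and the GC and length offset. Under the alternatives fixed in advance, no called gene was called in the opposite direction. With library totals alone the balance of calls turned, from 910 higher and 883 lower to 689 higher and 1019 lower. It turned also at 5 CPM or more (1121 and 1291), on FPKM + 1 (731 and 923), on FPKM + 0.1 (720 and 919) and without robust estimation (721 and 761). Higher genes stayed the more numerous with RLE factors, no filter, DESeq2, limma-trend on log2 CPM and the replicate block. The fall of YY1 kept its call throughout, at -1.61 to -1.72 with each library left out. Genes higher (910) became 1470 with DESeq2, genes changed at least 2-fold (234) became 55 on FPKM + 1 and 154 on FPKM + 0.1, and the lists higher (17) and lower (3) became 0 and 0 with an estimated correlation. With each library left out, genes higher were 425 to 2097, lower 595 to 1207, changed at least 2-fold 198 to 416, lists higher 13 to 19 and lists lower 1 to 3, where the lone sample was assumed to vary like the other group. The replicate block gave 1475 higher and 1427 lower; the labels do not say that equal numbers pair, and the replicate differences of the groups correlated at 0.004 over all tested genes and at 0.139 over those at 5 CPM or more. With the replicate block the heat shock and histone lists missed 0.05 (0.0606 and 0.0724). Without the words, 274 genes were lower and 85 changed at least 2-fold, among a smaller set of genes; the lists of antigen presentation (0.146), glycolysis (0.177) and heat shock genes (0.0931) no longer passed camera, and those of YAP/TEAD targets (lower, 0.0125) and TGF-beta targets (higher, 0.0408) did. With the GC and length offset 1760 were higher and 1495 lower, against 1157 and 1061 for the same genes without it. Where not shown by the construction, the cause was not tested. Transcript-level fits were not run because the file holds genes, and limma-trend and non-robust fits were not run for lists because camera already used log2 CPM.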

Other observations

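The proteasome tests here, like those of BACH1, of overlap at genes that jump between replicates and of the mitochondrial mRNAs without shNC replicate 1, were chosen only after the values were seen. Among 300 KEGG terms of the deposited table, 11 were higher and 0 lower by camera, and the proteasome had the smallest adjusted p (7.35e-07; adjusted p = 0.886 with an estimated correlation). Of its 42 tested members, 4 rose, 1 fell and 37 did not pass, 40 had a positive log2 fold change, and the median was 0.21. PSMC3, an ATPase of the regulatory particle (0.50 ± 0.0876), the deubiquitinase PSMD14 (0.40 ± 0.0749), the core subunit PSMA5 (0.44 ± 0.0982) and PSMD8 (0.34 ± 0.0824) rose, and the core subunit PSMB2 fell (-0.75 ± 0.0899), with TTCAGAA and TCAGAAA in its 3' UTR. PSMA5, which rose, holds TTCAGAA too. Among 1345 Reactome terms, 234 were higher and 3 lower by camera with the preset correlation, and with an estimated correlation the smallest adjusted p among the leading 200 terms was 0.824. The adjusted p of the proteasome term ranged from 3.05e-13 to 0.000391 over other scalings and left-out libraries.

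Many genes that were lower after YY1 knockdown shared a word in their 3' UTRs. Of 16252 words of 7 bases, TTCAGAA went with the lowest log2 fold changes (t = -23.2 over 9619 genes), whereas the most positive word, TCGGAGA, reached 6.79, and the largest t of TTCAGAA within a group was -2.22. The median log2 fold change fell from 0.08 without a site to -0.21 with the 8-base site TTCAGAAA, and for the other word rose from 0.03 without a site to 0.24 with the 8-base site TCGGAGAA, a grading consistent with seed-type silencing by a small RNA that differs between the groups, either a hairpin, whose sequence the labels do not give, or an endogenous microRNA. TTCAGAA occurs in the YY1 transcript, but so do 37.4% of all words, TCGGAGA among them, so this does not single out the hairpin. Higher genes were affected too: of 829 searched, 73 held TCGGAGA or CGGAGAA, against 23.8 expected from their 3' UTR length. Of the 38 at least 2-fold higher, 8 held one, against 0.87 expected. Among the 760 lower genes searched, 21 held one, against 30.7 expected. Of 760 lower genes searched, 506 held TTCAGAA or TCAGAAA, against 290 expected from the length of lower genes. At the rate of genes without a site, 105 lower calls were expected among genes with a word (an excess of 52.8% of lower calls). Among genes without any site, 3.54% were also lower. Only the annotated 3' UTR of the transcript with the longest coding sequence was searched, so sites elsewhere in these genes were not seen. Simulated counts also gave false calls, and effects of silenced genes on other genes were not tested. The rate of 3.54% therefore cannot decide whether sites account for all lower genes. A GC and length offset kept 96.6% of calls, so composition may not account for all of them.

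The mitochondrially encoded mRNAs stayed lower without shNC replicate 1, at a median of -0.29. The 13 mRNAs move together (estimated correlation 0.836) and that comparison rests on 1 shNC library, so a high mitochondrial share in shNC replicate 1 and an effect of the knockdown cannot be told apart.

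At 75 genes the counts jumped between replicates, as in TMEM189-UBE2V1 with 1550 and 0 counts in shNC and 0 and 695 in shYY1. Of these, 73.3% overlapped a gene on the same strand, against 24.9% expected at matched expression (permutation p = 1e-04, the smallest possible with 10000 draws). This is consistent with reads moved between overlapping genes by the counting, and 0 of the 75 genes were called by edgeR.

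The NRF2 list passed camera also without HMOX1 (adjusted p = 2.12e-05; adjusted p = 0.535 with an estimated correlation). BACH1, a repressor of HMOX1, fell from 19.2 to 8.08 CPM (log2 fold change -1.25 ± 0.179, edgeR adjusted p = 0.00423), and its 3' UTR holds TTCAGAA and TCAGAAA. Whether BACH1 has a part in the rise of HMOX1 was not tested. KEAP1 rose (0.34 ± 0.0865) and NFE2L2 (-0.02) did not pass.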
